A study of Homo sapiens with 5 samples.

How the data were processed

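K562 cells, a human chronic myelogenous leukaemia line, were profiled on 5 arrays, 2 of untreated cells and 3 of cells given a synthetic peptide for 9 h. Total RNA was reverse transcribed from an oligo-dT primer and amplified into Cy3-labelled cRNA, per the labels' protocols. Each sample was hybridised to 1 sub-array of a 1-colour Agilent human 8x60K slide. The groups and replicate numbers were taken from the sample labels. The labels give neither the dose or sequence of the peptide nor any sample given a vehicle or a control peptide, and nothing says that replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

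The deposited scanner tables hold spot intensities on a linear scale, made with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity is background-subtracted and detrended, with a substitute value for spots not significantly above background, per the file headers, and is not scaled between arrays. The authors' table of the whole series holds log2 values with gene names in rows, and the files do not state its scale. For 26770 genes with a single probe, 99.7 to 99.8% of its values lay within 0.01 of the log2 processed signal minus 1 constant per array. Its column medians were -3.84 and -3.85 for untreated replicates 1 and 2 and -3.93, -3.81 and -3.94 for treated replicates 1 to 3, with 75th percentiles of 0 to 0.009. The scale is thus log2 with the 75th percentile at about 0, and how several probes of a gene were combined stays unknown. The table served as an alternative.

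Control spots were left out, which left 58717 gene spots per array, 50599 probes and 36337 gene names. The log2 processed signal had each array's 75th percentile subtracted, so a value of 0 is that percentile. Spots with an outlier flag (416 to 541 per array) were left out, spots of a probe were averaged, and probes well above background on at least 2 of the 5 arrays were kept. The brightest remaining probe stood for a gene, which gave 18895 genes tested, 16290 of them well above background on all 5 arrays. There were 4314 genes with a further tested probe, and the median change of the further probes is given beside some of the named genes in the report. Gene names are those of the array design, annotated on hg19. The RefSeq gene table of assembly GRCh38.p14 gave a symbol for 21361 of the 36337 names, 19743 of them through the accession, 1264 by the same symbol and 354 through an older symbol. It was used for names only.

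No saturated spot was found, and 50.2 to 52.7% of the gene spots were well above background on each array. The number of arrays limits the precision. All 5 arrays lay on 1 slide and were scanned in 1 scan, with the untreated samples in slide row 1 and the treated samples in slide row 2. Slide row and treatment cannot be told apart.

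Treated and untreated arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are treated minus untreated on the log2 scale. Before the data were examined, 38 gene lists were fixed, and the 37 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry were run beside it. At the preset correlation camera takes its degrees of freedom from the number of genes, so its p-values do not reflect how few arrays there were. With an estimated correlation it is limited to the 3 residual degrees of freedom, and 0 of the 37 lists passed. A call lost there therefore does not single out a list. Calls within a list were also counted after adjustment over the list alone. The groups are too small for a count of other splits of the samples or for a search for single outlying samples. The lists, the main design and the rule for named genes were fixed before the data were examined. The rule took the DLX genes, DLX4 first. It took the 12 largest rises and 12 largest falls among symbol-named genes past the threshold that were well above background on all 5 arrays, with the 3 treated arrays on one side of both untreated ones. It took up to 4 members per list by smallest p, all tested globin genes, and up to 4 genes per direction measured in one group only. A few genes that the rule takes are not reported here. For the last kind, and wherever a probe was not well above background on any array of one group, the fold is a lower bound: the mean of the brighter group against the mean of the higher of each dim array's probe value and its lowest value well above background.

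After the data were seen, probes were marked that hold a run of at least 6 bases of alternating G and A, called a GA tract below, or 1 of 4 C-rich hexamers (CCCCGC, CCGCCC, CCCGCC, CGCCCC). The rule for the 12 largest rises and falls was repeated without them, and the comparison was repeated without such probes and with GC content and tract length regressed out.

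The alternatives planned before the data were examined were normexp background correction with an offset of 50, 3 other normalizations, 2 other filters on dim probes, 2 other ways to combine probes, keeping flagged spots, the authors' table, a trended robust prior, array weights, the replicate number as a block, leaving out each array in turn, limma's treat against a 1.5-fold change, and a test without moderation. The procedure was tested on simulated data for the same 18895 genes, 2 against 3 arrays, with the spread estimated from the data. With 200 changed genes it recovered 14.3% of those changed by 1 on the log2 scale, 80.0% of those changed by 2 and 96.7% of those changed by 4, with 6 false calls. With 1000 changed genes the shares were 63.6% at 1 and 92.4% at 2, with 41 false calls. The simulated noise was independent between genes, without variation shared across an array. The numbers of false calls therefore need not hold for the real arrays.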

Results

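Transcript levels were measured in K562 cells, a human leukaemia line that carries the BCR-ABL fusion and has erythroid features, without treatment (2 arrays) and after 9 h with a synthetic peptide designed to act as a transcription factor (3 arrays). Per the series title, the peptide imitates DLX4, a homeobox protein, or the isoforms of it known as DLX7 and BP1, and the comparison asks which genes change their expression when it is given. The 75th percentile of the processed signal was 210 and 219 on the untreated arrays and 203 to 244 on the treated arrays. Levels below are log2 signals relative to that percentile, as mean ± SD over 2 untreated and 3 treated arrays, and all adjusted p-values are from limma or its camera test. The probe of DLX4 itself (hg19 chromosome 17, 48051866 to 48051925) was well above background on all 5 arrays, at -1.82 and -1.58 on the untreated arrays and -1.66, -2.07 and -2.37 on the treated ones. Its log2 fold change of -0.33 ± 0.24 (SE) did not pass the test (adjusted p = 0.387). Of the other DLX genes, DLX1 (-0.41) and DLX2 (0.46) were measured without passing (adjusted p = 0.190 and 0.166). DLX3 and DLX5 were well above background on 0 of 5 arrays and DLX6 on 1.

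The treated cells had higher levels of inflammatory NF-kappaB target genes and of immediate early genes, which encode transcription factors and feedback regulators that respond within minutes to hours of a stimulus. Both lists passed camera at the preset correlation, and neither did with an estimated correlation (adjusted p = 0.123 for each). CXCL1, a neutrophil-attracting chemokine, rose by 3.84 on the log2 scale, FOSB, an AP-1 transcription factor subunit, by 3.96, and the cytokine gene IL6 by 2.27. Of the erythroid regulator and membrane protein genes 5 fell, KLF1 among them, as did 4 metallothionein genes, by 0.65 (LMO2) to 1.31 (MT2A). The globin genes HBG1 (-0.09, with -0.12 at its other probe), HBZ (-0.05, with 0.46 at its other probes) and HBA2 (0.22, with 0.24) did not pass.

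Of the 18 measured members of the NF-kappaB and inflammatory list, 9 rose and 0 fell, with a median log2 fold change of 0.92, against -0.15 for all genes tested. Adjusted over the list alone, 12 rose. The list passed camera (adjusted p = 1.76e-09) and fry (adjusted p = 0.00243), but not camera with an estimated correlation (adjusted p = 0.123). CXCL1 (probe at hg19 chromosome 4, 74736850 to 74736909) went from -2.00 ± 0.58 (n = 2) to 1.84 ± 0.06 (n = 3), a 14.3-fold rise (log2 fold change 3.84 ± 0.26 SE, limma adjusted p = 0.0266), and its other tested probe changed by 3.43. The related chemokine gene CXCL3 went from -1.35 ± 0.24 to 1.32 ± 0.11, a 6.38-fold rise. IL6 went from -1.10 ± 0.02 to 1.18 ± 0.18, a 4.84-fold rise. RELB, which encodes a subunit of the NF-kappaB complex, went from -0.10 ± 0.45 to 2.52 ± 0.08, a 6.15-fold rise. The adjusted p was 0.0266 for each of these 4 genes. The other members past the threshold, named after their values were seen, were TNFAIP3 (1.83) and NFKBIA (1.22), both feedback inhibitors of the pathway, CXCL2 (1.84, with 2.72 at its other probe), IL8 (now CXCL8, 2.34) and NFKB1 (0.92).

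Of 31 immediate early genes measured, 13 rose and 0 fell, with a median of 1.01 (0.90 with the EGR2, EGR3 and EGR4 values at their bounds), and 19 rose after adjustment over the list alone. The list passed camera (adjusted p = 3.88e-13) and fry (adjusted p = 0.00635), with a camera adjusted p of 0.123 at an estimated correlation of 0.0238. EGR2, a zinc-finger transcription factor, was not well above background in untreated cells and was at least 5.05-fold higher in treated cells (adjusted p = 0.0266). EGR4, measured on 2 of the 3 treated arrays and not above background in untreated cells, was at least 1.59-fold higher (adjusted p = 0.0266). The nuclear receptor gene NR4A2 rose by 1.30 ± 0.13 (SE), with an adjusted p of 0.0301, and its other probe changed by 0.88. EGR3 was at least 55.8-fold higher (adjusted p = 0.0302), on a probe with a GA tract of 7 bases, a feature that went with higher signal as described below. FOSB (probe at hg19 chromosome 19, 45978205 to 45978264) went from -2.60 ± 1.15 to 1.37 ± 0.17 (adjusted p = 0.0321). DUSP1 (1.18), ATF3 (1.29, with 0.69 at its other probes), KLF6 (1.14, with 0.80) and ZFP36 (1.24), named after their values were seen, also rose. FOS had a log2 fold change of 4.26 that did not pass (adjusted p = 0.069).

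**Figure D1:**
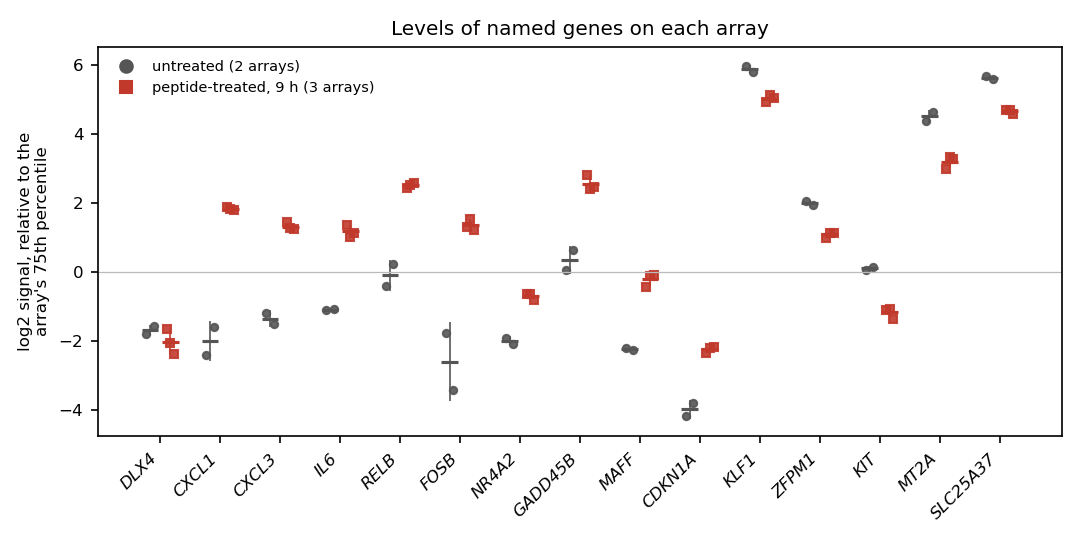
Level of 15 named genes on each array (vertical axis, log2 signal relative to the array's 75th percentile), with untreated arrays as circles and treated arrays as squares; horizontal lines are group means and vertical lines SDs. The treated arrays lie above both untreated arrays for CXCL1, CXCL3, IL6, RELB, FOSB, NR4A2, GADD45B, MAFF and CDKN1A, below them for KLF1, ZFPM1, KIT, MT2A and SLC25A37, and overlap them for DLX4.

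CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from -3.99 ± 0.27 to -2.25 ± 0.10 (adjusted p = 0.0287), and the stress-induced genes SESN2 and GADD45A rose by 1.79 and 0.74. These were the 3 of 21 p53 responsive genes that passed, and 0 fell, with a median of 0.05 (camera adjusted p = 0.0893). Over the 21 alternatives the log2 fold change of CDKN1A ranged from 0.48 to 1.93. Of 35 genes of endoplasmic reticulum stress and the amino acid response, 5 rose and 3 fell, with a median of 0.04. The risers included SESN2 and CHAC1 (1.07, with 1.88 at its other probe), a glutathione-degrading enzyme, while the endoplasmic reticulum chaperone genes PDIA4 (-0.96) and HSPA5 (-0.87) fell. That list passed camera (adjusted p = 0.0487), but not with an estimated correlation (adjusted p = 0.709) and not without untreated replicate 1 (median -0.10, adjusted p = 0.712), treated replicate 1 (0.0694) or treated replicate 3 (0.067). In the list of BCR-ABL and STAT5 responsive genes, 3 of 23 rose and 0 fell, namely ETV4 (1.22), ETV5 (1.29) and the cytokine signalling suppressor SOCS2 (0.86), with a median of 0.24 (adjusted p = 0.015). Its adjusted p was 0.708 with an estimated correlation and 0.358 without untreated replicate 2, where the median was 0.066. Without untreated replicate 1 the median was 0.488 (adjusted p = 6.78e-05). Of 31 proteasome genes, PSMA7 (0.98), PSMD7 (0.90) and PSMC5 (0.78) rose and 0 fell, with a median of 0.15 (adjusted p = 0.000497). With an estimated correlation the adjusted p was 0.708, and without untreated replicate 2 the median was 0.012 (adjusted p = 0.103), against 0.302 (adjusted p = 2.83e-05) without untreated replicate 1.

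A further 4 lists passed camera at the preset correlation with few or no members past the threshold. Like every other list that passed, they lost the call with an estimated correlation, where 0 of 37 lists passed. Among 29 autophagy and lysosome genes ATP6V0D1 rose by 0.84 and the protease gene CTSB fell by 0.86, with a list median of 0.12 (adjusted p = 0.00614, and 0.665 with an estimated correlation). Of 25 heat shock and chaperone genes 0 rose and HSPA1L fell, by 1.13, with a median of 0.18 (adjusted p = 0.0123, and 0.708 with an estimated correlation). None of 15 TGF-beta and BMP responsive genes passed on its own, with a median of 0.23 (adjusted p = 0.0487, and 0.665 with an estimated correlation) and 4 higher and 1 lower after adjustment over the list alone. Of 8 globin genes, HBQ1 rose by 0.79, on a C-rich probe, with a list median of 0.28 (adjusted p = 0.0487, and 0.708 with an estimated correlation). The globin list did not pass camera with GA-tract and C-rich probes left out. The embryonic globin gene HBE1 (0.53), HBD (0.34), HBB (0.49) and HBM (-0.04) did not pass. Of these 4, the heat shock list did not pass without untreated replicate 2 (median 0.105, adjusted p = 0.109), the autophagy list without untreated replicate 1 (median 0.182, adjusted p = 0.0501), and the TGF-beta and globin lists when any single array other than untreated replicate 1 was left out (adjusted p = 0.0551 to 0.119 and 0.0551 to 0.225). Without untreated replicate 2 the globin median was 0.026 and the autophagy median 0.269.

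Several groups of blood-cell genes had members that fell, without their list passing camera. Of 30 erythroid regulators and membrane proteins, 5 fell and 0 rose, with a median of -0.20 (camera adjusted p = 0.262, fry adjusted p = 0.0297). Among them were KLF1, a master regulator of red-cell genes, from 5.89 ± 0.13 to 5.03 ± 0.10 (adjusted p = 0.0391), the GATA1 cofactor gene ZFPM1 (-0.91), EPB41 (-1.09, with -0.16 at its other probe) and LMO2 (-0.65, named after its value was seen). Of 16 genes of heme synthesis and mitochondrial iron, the iron importer gene SLC25A37 fell by 0.98 and UROS rose by 0.74 (0.62 at its other probes), with a median of 0.03 (adjusted p = 0.366). Among 14 growth factor, cytokine and receptor genes of blood cells, KIT, the stem cell factor receptor, fell by 1.27 (adjusted p = 0.0302), and CCR7 (0.86, on a GA-tract probe) and NOTCH2 (0.82, with -0.83 at its other probe) rose (list median -0.54, or -0.46 with 1 member at its bound, adjusted p = 0.274). Of 13 metallothionein and metal response genes, 4 fell and 0 rose, with a median of -0.56 (adjusted p = 0.137), and 9 fell and 1 rose after adjustment over the list alone. The list passed camera in 2 of 21 alternatives, with no filter on dim probes (adjusted p = 0.038) and with GC content and GA-tract length regressed out (adjusted p = 0.022). MT2A went from 4.52 ± 0.19 to 3.21 ± 0.18 (adjusted p = 0.0325), and MT1L, MT1E and MT1B fell by 1.19, 1.27 and 1.19, with -0.28 at the other probe of MT1E. Metallothionein genes are near-identical in sequence, so their probes may not tell them apart.

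Markers of other cell types did not rise together. Of 12 granulocyte and monocyte markers, CD14 rose by 1.13 and SPI1 fell by 0.69 (median -0.53, adjusted p = 0.357). Of 8 lymphocyte markers, 2 fell, CD4 by 1.85 among them, and CD3E rose by 4.62 on a GA-tract probe (median -0.71, mean 0.03, adjusted p = 0.532). None of 10 epithelial and stromal markers (median -0.13, adjusted p = 0.918) and none of 9 megakaryocyte markers (median -0.02, adjusted p = 0.914) passed.

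The remaining lists did not pass camera, and most of their members did not pass alone. Of 10 genes linked to DLX4, DLX7 or BP1 in earlier work, CDKN1A rose and BRCA1, a DNA repair gene, fell by 0.63, while ICAM1 (0.34) and HBB (0.49) did not pass (median 0.02, adjusted p = 0.298). In the 30 homologous recombination and repair genes, BRCA1 and BRCA2 (-0.80) fell (median -0.21, adjusted p = 0.293). Of 38 G2 and mitosis genes KIF20A fell by 0.72 (median -0.26, adjusted p = 0.293), and of 38 replication genes GINS4 fell by 0.74 (median -0.02, adjusted p = 0.262). Of 52 replication-dependent histone genes, 1 rose and 3 fell (median -0.20, adjusted p = 0.298), their paralogs being hard to tell apart by probe. Of 15 HOX genes HOXC8 fell by 1.09 (median -0.39, adjusted p = 0.138). Of 13 cyclin-dependent kinase inhibitor and quiescence genes CDKN1A rose (median -0.09, mean 0.12, adjusted p = 0.274). Of 26 pro-apoptotic genes PMAIP1 rose by 0.93, and APAF1 and BNIP3L fell by 1.07 and 0.71, with -0.42 at the other probes of BNIP3L (median -0.05, adjusted p = 0.492), while 0 of 14 anti-apoptotic genes passed (median 0.05, adjusted p = 0.428). Of 27 NRF2 and oxidative stress genes GPX1 fell by 0.98 (median -0.03, adjusted p = 0.473), and of 32 hypoxia and glycolysis genes the glucose transporter gene SLC2A1 fell by 0.81 (median 0, adjusted p = 0.138). Of 36 MYC responsive and ribosome biogenesis genes SRM rose by 0.91 (median 0.01, adjusted p = 0.0887). Of 77 cytosolic ribosomal protein genes RPS3 rose by 0.88 (median -0.04, adjusted p = 0.274). Of 59 nuclear-encoded oxidative phosphorylation genes 4 rose, 3 of them on probes without a GA tract, SDHB by 0.95 among these, and NDUFS7 fell by 0.72 (median -0.04, adjusted p = 0.137). Of 25 cholesterol synthesis genes STARD4 rose by 0.93 and 1 fell (median -0.12, adjusted p = 0.981). Of 25 actin cytoskeleton and SRF target genes MYL6 rose by 0.77 (median 0.02, adjusted p = 0.0887). Of 35 chromatin modifiers SETDB1 fell by 0.56, with 0.05 at its other probes, and SMARCA4 rose by 2.23 on a probe with a GA tract of 15 bases (median 0.02, adjusted p = 0.367). None of 35 splicing factors (median -0.03, adjusted p = 0.468) or 23 interferon stimulated genes (median -0.15, adjusted p = 0.81) passed.

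**Figure D2:**
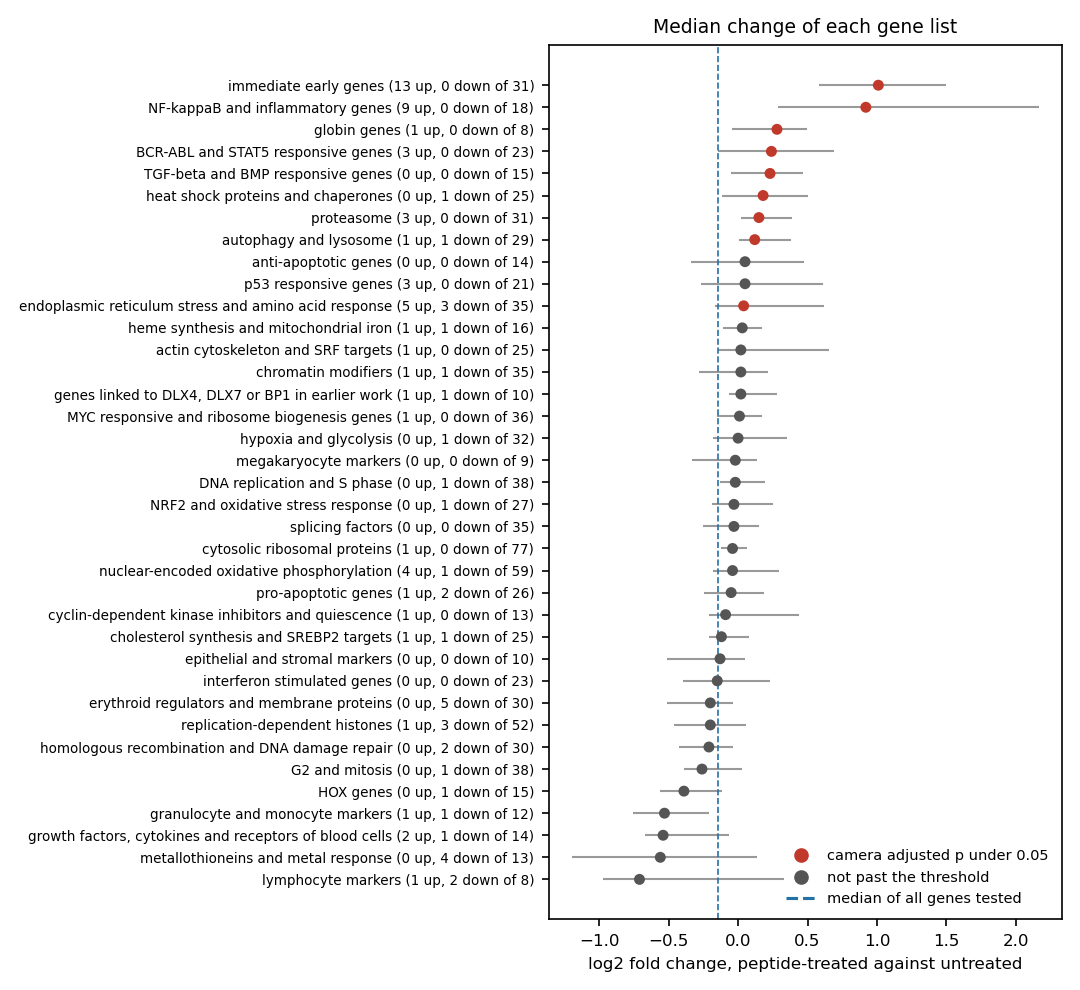
Median log2 fold change, treated against untreated, of each gene list with at least 5 measured members (points) with the quartiles of its members (lines); the dashed line is the median of all genes tested, -0.15, and the counts are members past the threshold. The immediate early and NF-kappaB lists, at 1.01 and 0.92, stand apart from the other lists, which lie between -0.71 and 0.28.

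Over all 18895 genes, 1385 passed the threshold, 623 of them higher and 762 lower in treated cells, and 717 of them had a fitted change of 2-fold or more, 391 higher and 326 lower. Of the 717, 145 were on a probe not well above background on any array of one group, which gives only a bound. With those at their bound, 658 changed at least 2-fold, 386 higher and 272 lower. Scaling to the 75th percentile of the probes above background on all arrays gave 572 higher and 357 lower, and scaling to the median 480 higher and 386 lower, so the split between directions depended on the scaling. The first principal component (70.2% of the variance), computed with GA-tract probes included, separated the groups. Correlations were 0.981 to 0.988 within groups and 0.929 to 0.962 between them. Without GA-tract probes they were 0.983 to 0.988 within groups and 0.968 to 0.978 between them, so those probes carried much of the separation. The smallest adjusted p was 0.0266, and the count depended on single arrays: leaving out 1 array gave 1564 (untreated replicate 1), 24 (untreated replicate 2), 337 (treated replicate 1), 0 (treated replicate 2) and 211 genes (treated replicate 3). The immediate early and NF-kappaB lists passed camera without each of the 5 arrays at the preset correlation (adjusted p = 0.123 for each with an estimated correlation and all arrays).

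The largest rises went with a feature of the probe sequence. The 12 largest rises by the fixed rule were REP15 (8.07), KRT79 (7.91), OSTBETA (now SLC51B, 7.33), GPR182 (7.33), OR52E8 (7.32), BICC1 (7.32), PROM2 (7.26), GPR179 (7.14), CCDC66 (7.02), HMBOX1 (6.99), TEF (6.92) and BCR (6.79), and the probes of all 12 held a GA tract. HMBOX1 and BCR, a partner of the fusion gene of this line, had other tested probes, whose median changes were -0.13 and -0.02. The median log2 fold change was -0.17 for 12120 genes whose probe had no alternating run of 4 bases, -0.01 for 460 genes with a run of 6, 1.07 for 219 genes with a run of 7, 5.48 for 112 genes with 8 and 6.86 for 32 genes with 10 or more. With probes not well above background in a group at their bound, the medians were 0.73 at 7 bases, 4.75 at 8 and 6.86 at 10 or more. On the same terms, 195 genes past the threshold were at least 16-fold higher, and 190 of them had a GA tract. Without such probes, a choice made after seeing the data, 894 genes passed, 306 higher and 588 lower, of which 146 and 280 had a fitted change of 2-fold or more. The 12 largest rises on other probes were then WNT2B (5.17), FOSB, CXCL1, RRAD (2.91), SPEF1 (2.75), CXCL3, RELB, IL6, RFX8 (2.23, with 0.32 at its other probe), the stress gene GADD45B (2.23), CSRNP1 (2.05, with 2.06 at its other probe) and the transcription factor gene MAFF (2.03). The probes of WNT2B, FOSB and GADD45B had a run of 5 bases and those of RRAD, RELB, RFX8 and CSRNP1 a run of 4. The median was -0.14 for the 1595 genes with a run of 5 and -0.15 for the 4318 with a run of 4. Past the threshold, 52 and 98 of these rose, against 234 of the 12120 without a run. The medians therefore do not exclude an effect of the run on single probes. WNT2B had no other tested probe, and its SDs were 0.78 on untreated and 1.23 on treated arrays.

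**Figure D3:**
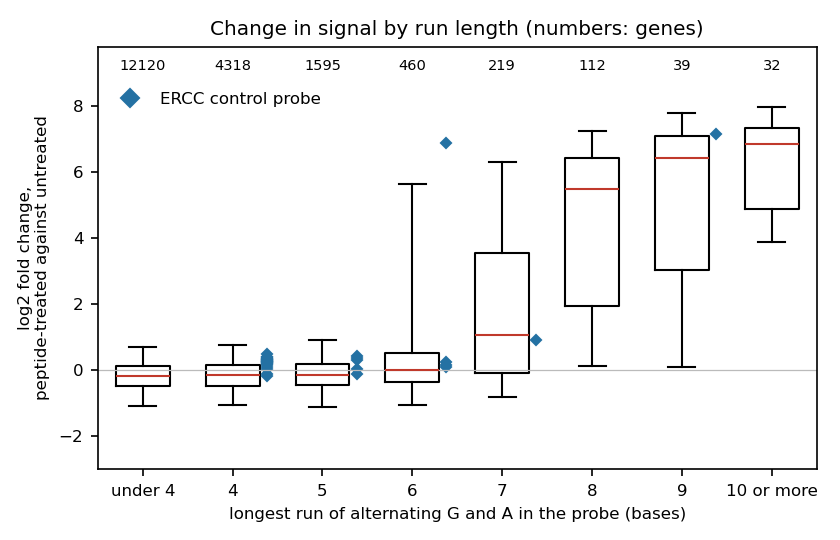
Fitted log2 fold change (no bounds), treated against untreated, of the genes tested by the longest run of alternating G and A in their probe; boxes are quartiles with the median, whiskers the 5th and 95th percentiles, numbers above are genes, and diamonds are control probes of non-human ERCC sequences with a run of at least 4 bases, 2 of them well above background on any array. The median rises from -0.17 below 4 bases to 6.86 at 10 or more, and the ERCC probe with a run of 9 bases lies at 7.16.

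The 12 largest falls were NPB (-3.03), EVX1 (-2.89), FOXB1 (-2.82), TUSC1 (-2.38), CCDC78 (-2.36), SORBS3 (-2.23), CRTC1 (-2.21, with -1.24 at its other probe), OGFR (-2.17, with -0.23), YJEFN3 (-2.08, with -2.35), OSCAR (-2.01, with -0.11), KCNQ1OT1 (-2.01) and CBX3P2 (-1.98). NPB, FOXB1, OGFR and OSCAR were on C-rich probes, whose median change was -0.65 over 325 genes. Without these 4, the next in size were HINT3 (from 4.08 ± 0.26 to 2.22 ± 0.11, adjusted p = 0.0266), CD4, B3GALT6 (-1.80) and BHLHE23 (-1.79). Of the genes well above background on every array of one group and no array of the other, 108 were in treated cells (3 arrays), 78 of them with a GA tract, and 477 in untreated cells (2 arrays). Detection differed between the groups, with 52.65 and 52.56% of gene spots well above background on untreated arrays and 50.16 to 50.36% on treated ones. The counts 108 and 477 therefore cannot be compared directly. The bound was above 1-fold for all 108 and for 411 of the 477. By the bound, EGR3, DPRX (at least 41.8-fold), ZNF806 (39.8-fold) and ZCCHC13 (38.5-fold) were highest in treated cells, all on GA-tract probes. In the other direction S1PR4, a sphingosine-1-phosphate receptor gene, was at least 2.81-fold lower in treated cells (adjusted p = 0.0266), and AGBL2, RBM26-AS1 and RTP3, at least 3.91-, 3.18- and 3.14-fold lower by the bound, did not pass (adjusted p = 0.0864, 0.0552 and 0.0775).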

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

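The tests on other probes of the same genes and on neighbouring spots were set before their results were seen. The marking of GA tracts itself was chosen after seeing the data. The array carries control probes that were left out of the gene tests, and 4 of them were well above background on all 3 treated arrays, higher there than on both untreated arrays, and at least 2-fold brighter in mean signal. The control probe ERCC-00113_271, with a GA tract of 9 bases, had a mean of -2.41 ± 0.91 on the untreated arrays and 4.74 ± 0.82 on the treated arrays, a log2 difference of 7.16. ERCC-00018_67, with a tract of 6 bases, was not well above background on the untreated arrays and at 0.89 ± 1.25 on the treated ones, at least 47.7-fold higher (the signals themselves differ by 6.87). ERCC-00142_99 and ETG09_35454, without a tract, differed by 1.02 and 1.36. ERCC sequences are synthetic spike-in standards designed not to match human transcripts. The other 4 ERCC probes with a tract, and 74 of the 78 without a tract, were not well above background on any array, so no difference can be given for them.

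Probes with a GA tract were brighter on the treated arrays for many human genes, mostly from 7 bases on, and so were 2 of the 6 ERCC probes with a tract. Of 230 genes called at least 2-fold higher on such a probe, 38 had another tested probe without a tract. The tract probes of the 38 had a median log2 fold change of 5.97 (5.89 with probes not well above background in a group at their bound). Their other probes had a median of -0.29 (95% interval over genes, not arrays, -0.47 to -0.02). Of the 38 genes, 0% had another probe that passed with a rise. This argues against a rise of the genes' own transcripts, and fits a labelled sequence that binds GA tracts. A patch of the slide is argued against by the 475 neighbouring spots without a tract, whose median lay 0.04 above that of all such spots, and by the spread of the bright spots over all 32 of 32 slide blocks. Where such a sequence came from (a repeat-rich transcript of the treated cells, material that came with the peptide, or a step of labelling) stays open. Each treated array had it, but it need not be confined to them. ERCC-00113_271 was well above background on both untreated arrays too, at a mean of -2.41. If that signal has the same source, material that came with the peptide cannot be the only one. ERCC-00142_99, without a tract, was also above background there, at -3.26, so the signal may have another source.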

How the results depend on the processing

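The alternatives without GA-tract or C-rich probes and with GC content regressed out were chosen after seeing the data, the others before. The immediate early and NF-kappaB lists passed camera at the preset correlation in all 21 alternatives, with medians of 0.58 to 1.20 and 0.51 to 1.16. The number of genes past the threshold, 1385, was 2477 with normexp, 2480 with only probes above background on all 5 arrays, 3004 with a trended robust prior, 866 with median normalization, 894 without GA-tract probes, 49 without moderation, and 0 with no filter on dim probes or with array weights. At an unadjusted p under 0.05 the last 2 gave 7126 and 4844 genes. The cause was not tested. The number with a fitted change of 2-fold or more, 717, was 426 without GA-tract probes, 439 without GA-tract and C-rich probes, 62 with limma's treat, and 0 with no dim filter or with array weights. Leaving out 1 array gave 0 to 1564 genes past the threshold, 0 to 923 of them fitted at 2-fold or more, and 5 to 9 lists. Without an untreated array the lone one is assumed to vary like the treated ones. The number of lists past the threshold, 9, was 14 with the mean of all probes of a gene, 3 with fry and 0 with an estimated correlation. The 3 with fry were the NF-kappaB and immediate early lists and, lower in treated cells, the erythroid regulator list, which is not among the 9. The rest of the 9 did not pass fry. The lowest within-group correlation exceeded the highest between-group one by 0.0185, and by 0.0052 without GA-tract probes. With the replicate number as a block, which leaves 1 residual degree of freedom, 314 genes passed, all with a fitted change of 2-fold or more. Same-numbered samples did not deviate together (correlations 0.01 and -0.065), which gave no sign of pairing. The deviations of the 2 untreated arrays mirror each other, so these values cannot exclude pairing.

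Of 190 named genes, 106 passed, 47 of those were called in at least 14 of the 21 alternatives, and 7 turned direction in at least 1. The 7 were HMBOX1 (-0.23) and BCR (-0.17) without GA-tract probes, also without C-rich ones. They were CD3E (-0.32) and SMARCA4 (-2.73) with GC content and tract length regressed out. They were NOTCH2 with the mean of all probes (-0.004), and YJEFN3 (1.76), UROS (-0.023) and NOTCH2 (-0.033) in the authors' table. SETDB1, BRCA1 and SPI1 were called in 4, 5 and 6 alternatives, and the globin, TGF-beta and endoplasmic reticulum stress lists in 12, 9 and 11. FECH, not called at -0.49, was 3.06 in that table. Its way of combining probes is not stated. The median of the cytosolic ribosomal protein list turned positive, with a camera call, under quantile normalization (0.025), the mean of probes (0.008), every probe on its own (0.010) and the GC regression (0.085), the last also for oxidative phosphorylation (0.081). With 1 array left out the median of the endoplasmic reticulum stress list ranged from -0.10 (without untreated replicate 1) to 0.23 and that of the splicing factors from -0.25 to 0.20 (without untreated replicate 1). Signal over background limits genes such as EGR2, EGR4 and S1PR4 to bounds.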

Other observations

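The tests on GA tracts, on single arrays and on other cell types for the NF-kappaB and immediate early genes were chosen after the result was seen. Some genes outside the fixed lists are named here after their values were seen. INHBE, which encodes an activin subunit, rose by 1.55, the stress-induced gene ZFAND2A by 1.53 and G0S2 by 1.25. CD70, a TNF family ligand gene, fell by 1.47 and CBFA2T3, which encodes a corepressor of blood cell development, by 1.46. Within the list of endoplasmic reticulum stress and the amino acid response, PPP1R15A (1.21), TRIB3 (0.78) and ATF3 (1.29) rose beside SESN2 and CHAC1, and CRELD2 (-0.61) fell beside PDIA4 and HSPA5, chaperone and folding genes.

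The 47 NF-kappaB and immediate early genes measured on probes without a GA tract had a median log2 fold change of 0.93 (95% interval over genes 0.62 to 1.30). With 2 of them at their bound the median was 0.91 (0.62 to 1.24). These intervals treat genes as independent and hold no spread between arrays. Of the 47 genes, 42 were above 0, which argues against GA tracts in their probes. The lowest median of these genes of both lists with 1 array left out was 0.91, which argues against a single array. With probes filtered anew, the NF-kappaB list alone had medians of 0.67 without untreated replicate 1 and 1.16 without untreated replicate 2. Those of the immediate early list were 1.05 and 0.98. Among 29 markers of granulocytes and monocytes, lymphocytes, or epithelial and stromal cells on such probes, 1 (CD14) rose and 3 fell, with a median of -0.49 (-0.37 with 2 at their bound). The markers thus did not rise as a set. A small admixture of a single cell type cannot be excluded, since few markers per type were tested and small changes are often missed. Handling of the treated cultures other than the peptide stays open, since 0 arrays hold cells handled alike without peptide, and so does the slide row. A response of the cells to the peptide is a hypothesis that these samples cannot separate from them.

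Probes rich in C were dimmer on the treated arrays in their median (-0.65 over 325 genes). Past the threshold, 10 of the 325 fell, against 762 of all 18895 genes tested, so single C-rich probes were not called more often. Of 91 genes whose C-rich probe fell by 1 or more on the log2 scale, 28 had another tested probe without a C-rich run. The C-rich probes of the 28 had a median of -1.57 and the others -0.14 (95% interval over genes, not arrays, -0.38 to 0.15), a test set before its result was seen. Over all 78 genes with both kinds of probe the medians were -0.78 and -0.17, so picking low probes does not account for the whole gap. A candidate explanation is the sequence of the probe, and a fall of the genes' transcripts as a biological alternative is not what the other probes showed. What in the samples changed such hybridisation was not tested.

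The 8 brighter E1A control probes differed by -0.41 to -0.15 between treated and untreated arrays, with a median of -0.35, while the median of all genes tested was -0.15. Genes whose probe had 6 or more bases of alternating T and C, the opposite strand of a GA tract, numbered 571 and had a median log2 fold change of -0.23.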
